A study of Mus musculus with 4 samples.

How the data were processed

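Gene expression and surface protein were measured in sorted CD11b+ cells of MC38 tumors by 10x Genomics 3 prime v3.1 sequencing with feature barcoding, per the labels. The series has 4 samples in 4 groups of 1 each: a WT and a VISTA KO gene expression library, and the WT and VISTA KO antibody tag libraries made from the same cells. The labels give a minimum of 20000 read pairs per cell for gene expression and 5000 for tags. The deposited matrices hold counts: whole-number UMI counts for 32285 genes and 3 antibody tags per cell barcode, with no normalization. Per the file headers they were written by Cell Ranger 5.0.0, and per the submitters' processing notes the reads were aligned to mm10 with Cell Ranger and Seurat 4.0 was used, though the step it served is not given in the sources used here. The settings by which cells were called are not given in the sources used here either. No reads were realigned. Gene positions came from a RefSeq annotation of GRCm38.p6, the assembly behind mm10.

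Cells were kept with at least 200 genes, at least 500 gene UMIs and at most 10% mitochondrial UMIs, which left 99.5% of WT and 99.2% of VISTA KO barcodes. Kept cells had a median of 4692 UMIs in WT and 4212 in VISTA KO, and 47 barcode sequences occurred in both libraries and were treated as separate cells. Scrublet, as run by scanpy 1.11.5 with 0.8% doublets expected per 1000 barcodes, called only 1 droplet of both libraries a doublet, so the caller had not worked. Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen per library without Vsir, mitochondrial, ribosomal, Xist, Y-linked and cell cycle list genes, and 30 principal components with 15 neighbours went into Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 7). Gene symbols that occur more than once in the matrices were read from their first entry.

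Clusters were named from 17 fixed lists of cell type markers. A marker supported a name where its mean was at least 1.5-fold above that of other cells and at least 20% of the cluster's cells held it, and at least 3 supporting markers were required. A cluster of another type was called mixed where at least 3 macrophage markers were each found in at least 60% of its cells. A cluster was left unnamed where it had fewer supporting markers, more markers of another type among its 10 leading genes, or low counts and no own marker among them. These naming thresholds were set after the clusters had been seen. Names carry the ending -like because they rest on RNA of markers alone.

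UMIs were summed over the cells of a class in each library and given per 1000000 UMIs of that sum (CPM). The log2 ratio is VISTA KO over WT with a pseudocount of 1 UMI per sum, except for Vsir in the comparison of its own level, which has no pseudocount. Its 95% interval is the exact conditional binomial interval of a ratio of Poisson counts. Levels have exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals and differences of shares Newcombe intervals. With 1 library per group no test was run, no p-value was computed and cells were not used as replicates. No paired analysis was possible because each group held 1 library. Ratios were computed for all kept cells and for each class with at least 100 cells in both libraries. Shares of cells with a UMI were also computed after thinning each cell to 1000 UMIs without replacement, leaving out cells below that depth.

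For 23 fixed programme lists and 1 technical list, the median log2 ratio of members with at least 20 UMIs was computed in each class, with its percentile among 10000 random lists matched on expression in 20 bins. A member was counted as higher or lower where its ratio was at least 1.25-fold, the size rule for lists, and its interval left out 1. Genes were counted at a size of 1.5-fold in the same way, among genes with at least 100 UMIs. Of the listed symbols, 7 are not in the matrices. The named genes were fixed by rule: among genes with at least 100 UMIs in a class and found in at least 5% of its cells in either library, the 10 highest and 10 lowest ratios in neutrophil, monocyte and macrophage classes and the 5 highest and 5 lowest elsewhere and in all kept cells. Mitochondrial, ribosomal, Xist, Y-linked, Gm and Rik genes were left out of that ranking. Beside these stand Vsir, up to 4 members per list (the 2 highest and 2 lowest with at least 100 UMIs) and any gene of the polyamine and STAT3 lists. The markers, lists, rule and first set of alternatives were written before the data were examined. Not every gene that the rule allows is printed.

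The ratio method was tested on simulated data made from the observed monocyte-like and macrophage-like sums. In the monocyte-like simulation, 32 of 67 genes set at 1.5-fold, 64 of 64 at 2-fold, 64 of 64 at 4-fold and 24 of 8542 unchanged genes passed the 1.5-fold rule, and 95.2% of intervals held the true ratio. In the macrophage-like simulation the numbers were 32 of 65, 62 of 63, 57 of 57, 49 of 8897 and 95.5%. Unchanged lists fell outside the middle 95% of random lists in 3 of 50 and 2 of 50 runs. These simulations hold counting error only and no spread between animals.

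The alternatives tried were other cell filters (500 genes, 1000 UMIs and 5% mitochondrial, or no lower limit), doublets kept, Leiden resolutions 0.5 and 2, clustering each library alone, scaling by the median ratio, equal weight per cell, thinned cells and other count limits. Further alternatives were added after the data had been seen: leaving out the highest Scrublet scores, clustering without 1066 genes that mark the library (within 40 Mb of Ptprc, 10 Mb of Vsir and of Pianp, and the MHC class II list), leaving out mixed and unnamed clusters, leaving genes near Ptprc, Vsir and Pianp out of the counts, equal weight per cluster, and leaving out cluster 6 from the monocyte-like class. Of the gene values that reversed under an alternative, all but 1 are given with the sensitivity results, and that 1 is not reported here. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.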

Results

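The series addressed what loss of VISTA, an inhibitory receptor of myeloid and T cells encoded by Vsir, does to myeloid-derived suppressor cells (MDSCs) in tumors, with STAT3 and polyamines named in its title. Bone marrow chimeras were made from WT and VISTA KO donors of the C57/BL6 strain and were given MC38 tumors, a transplanted mouse colon carcinoma, after 6 weeks of reconstitution. Tumors 9 to 10 mm wide were pooled and digested. WT and KO cells were told apart by CD45.1 and CD45.2, and viable CD11b+ cells were sorted. Each group, WT and VISTA KO, held 1 gene expression library and 1 library of antibody tags for CD11c, Ly6G and Ly6C. The WT library held 10241 barcodes with 61753547 gene UMIs and a median of 4678 UMIs per barcode. The VISTA KO library held 15257 barcodes with 80366761 gene UMIs and a median of 4189. Both barcode numbers were above the 10000 cells loaded per the labels. After filtering, 10193 WT and 15139 VISTA KO cells were kept. With 1 library per group there was no replicate check, and every 95% interval covers counting error only.

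Vsir RNA was compared first, since the groups are defined by this gene. In all kept cells Vsir (ENSMUSG00000020101, chromosome 10, 60346851 to 60430294 on mm10) stood at 136.5 UMIs per 1000000 (CPM; 133.6 to 139.4) in the WT library and 46.2 (44.7 to 47.7) in the VISTA KO library. These values rest on 8423 and 3706 UMIs, and the VISTA KO level was 33.8% of the WT level. Vsir was lower in the VISTA KO library in monocyte-like cells (134.2 against 32.9 CPM) and in macrophage-like cells (154.1 against 70.8). It was also lower in NK cell-like cells, at 40.4 against 6.76. In fibroblast-like cells, which should lack Vsir, it stood at 55.1 and 47.3, from 20 and 23 UMIs. Fibroblast-like cells of a chimera need not come from the donor. Their value is no background level for the VISTA KO library, where NK cell-like (6.76) and mature DC-like cells (14.6) held less. With cells thinned to 1000 UMIs, 12.7% of WT cells (561 left out, 45.1% unthinned) and 4.13% of VISTA KO cells (1561 left out, 18.0% unthinned) held a Vsir UMI. The same share in fibroblast-like cells was 5.56% (0.680 to 18.7) for WT and 1.52% (0.0384 to 8.16) for VISTA KO, with median depths of 6608 and 4646 UMIs before thinning against 4692 and 4212 over all kept cells. The sources used here do not say which part of the gene was deleted, and a 3 prime tag outside the deleted part checks nothing about the genotype.

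The share of each cell class among sorted CD11b+ cells was compared to see which myeloid cells each library held. Droplets with neutrophil RNA made up a far smaller part of the VISTA KO library: neutrophil-like and mixed neutrophil and macrophage droplets together took 22.3% of WT cells (21.5 to 23.1) and 5.68% of VISTA KO cells (5.32 to 6.06). Macrophage-like cells took 12.7% of WT (12.0 to 13.3) and 23.7% of VISTA KO cells (23.02 to 24.38). Monocyte-like cells, the class closest to monocytic MDSCs, took 33.4% of WT (32.5 to 34.3) and 27.8% of VISTA KO cells (27.1 to 28.6). NK cell-like cells took 4.97% and 2.63%, and T cell-like cells 1.41% and 0.0991%, from 144 and 15 cells. Conventional type 2 dendritic cell-like (cDC2-like) cells, at 4.50% and 4.72%, and mature dendritic cell-like (mature DC-like) cells, at 1.71% and 1.72%, were close between the libraries.

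Only 392 WT and 77 VISTA KO droplets were neutrophil-like by themselves. The other 1881 WT and 783 VISTA KO droplets formed cluster 2, with a median of 9648 UMIs in WT and 10297 in VISTA KO. Cluster 2 as a whole was named mixed, as 9 macrophage markers were each found in at least 60% of its cells. Its droplets held a mean of 22.5 UMIs of the macrophage marker C1qa in WT and 25.2 in VISTA KO. Summed over each whole library, the neutrophil marker genes (S100a8, S100a9, Cxcr2 and 9 others) stood at 5438 and 1503 CPM. The macrophage marker genes stood at 10285 and 13314, and the monocyte marker genes at 12188 and 11314. Cluster 0 held most macrophage-like cells of the VISTA KO library, 2615 of 3587, against 620 of 1292 in WT. Monocyte-like cells of the WT library lay mostly in clusters 1 and 5, with 1602 and 848 of 3405 cells, while in VISTA KO cluster 6 was the largest, with 1338 of 4216 cells against 179 in WT. Cluster 6 met the naming rule with only 3 supporting markers, and a cluster with Cxcl9, Ly6i and Anpep among its leading genes, as cluster 6 has, was left unnamed with the stricter cell filter (291 WT and 2588 VISTA KO cells), with no lower limit on genes and UMIs (147 and 1083), at Leiden resolution 2 (172 and 1377) and in the VISTA KO library clustered alone (2476). Clusters left unnamed, by thresholds set after the data were seen, took 15.3% of WT and 29.7% of VISTA KO cells. Most of the VISTA KO surplus there lay in cluster 3, with 284 WT and 1869 VISTA KO cells, and in cluster 4, with 183 and 1655. Cluster 3 was led by Ifi202b, a gene far higher in the VISTA KO library. It had 7 macrophage markers each in at least 60% of its cells, so the macrophage-like share depends on its naming. Cells of cluster 4 had low counts and a median of 2.30% mitochondrial UMIs in WT and 3.47% in VISTA KO.

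The CD11b+ sort set the frame of these shares, and the libraries differed in depth. Scrublet found 0 doublets in WT and 1 in VISTA KO although 8.19% and 12.2% would follow from the barcode numbers, so doublets were in effect kept. The macrophage-like difference, 11.0 percentage points, was 4.40 when genes that mark the library were kept out of the clustering, 3.07 when each library was clustered alone and 18.0 when mixed and unnamed clusters were left out. The neutrophil difference of -16.6 points was -5.25 with mixed and unnamed clusters left out, which takes the mixed droplets out of the class itself and leaves 6.07% of WT and 0.817% of VISTA KO cells. The monocyte-like difference of -5.56 points lay between -13.6 and -7.10 under the alternatives. The NK cell-like difference of -2.35 points was -0.977 when each library was clustered alone, and of NK cell-like and mixed NK cell and macrophage droplets together 19.7% in WT and 33.0% in VISTA KO were mixed.

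**Figure D1:**
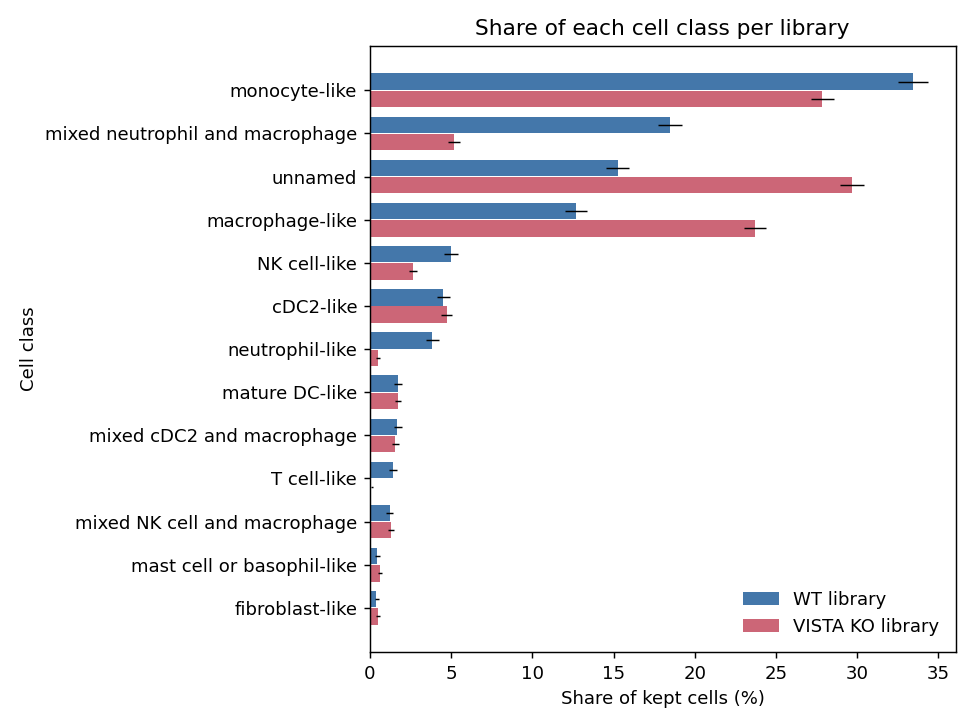
Share of kept cells per class (percent, x axis) in the WT and VISTA KO libraries, with exact 95% binomial intervals as lines, 1 library per bar. Mixed neutrophil and macrophage droplets stand at 18.5% and 5.17%, and macrophage-like cells at 12.7% and 23.7%.

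Antibody tags on the same cells were compared to set surface protein beside RNA. Ly6G, the neutrophil antigen, had a median of 63 tag UMIs per neutrophil-like WT cell and 43 per VISTA KO cell. Mixed neutrophil and macrophage droplets carried a median of 83 and 50 Ly6G tags. Macrophage-like cells had 8 and 5, monocyte-like cells 4 and 3, and NK cell-like cells 1 and 1. Ly6C, the antigen of inflammatory monocytes, had medians of 1004 and 919.5 per monocyte-like cell and 968.5 and 917 per macrophage-like cell. CD11c, an integrin of dendritic cells and macrophages, had medians of 19 in macrophage-like cells of both libraries, 5 and 7 in monocyte-like cells, 27 and 17 in cDC2-like cells and 52.5 and 33 in mature DC-like cells.

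Gene expression was compared within monocyte-like cells, 3405 WT and 4216 VISTA KO, where the title's question on MDSC differentiation applies most directly. Antigen presentation genes of MHC class II were higher in the VISTA KO library: 12 of 13 measured members were higher and 0 lower, with a median log2 ratio (VISTA KO over WT) of 0.96. A member of a list counted as higher or lower where its ratio passed the size rule for lists and its counting interval left out 1. H2-Eb1, a class II beta chain, stood at 374.1 CPM in WT and 2164 in VISTA KO (log2 ratio 2.53, 2.49 to 2.57). H2-Aa, the alpha chain of the I-A molecule, had a log2 ratio of 2.33, and Cd86, a costimulatory ligand of T cells, 0.47. The list median was 0.56 without cluster 6 and 0.27 when each library was clustered alone. Clustering alone left a VISTA KO cluster with leading genes of cluster 6 unnamed and so out of the monocyte-like class. C1qb and H2-Aa RNA in NK cell-like cells, which should lack both, was also higher in VISTA KO, at 267 against 45.5 and 432.7 against 75.8 CPM.

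Inflammatory genes also differed in monocyte-like cells. Of the 20 NF-kappaB feedback genes and targets, 17 were higher and 0 lower in VISTA KO (median 0.45), with Bcl2a1d, an antiapoptotic BCL2 relative that shares reads with close copies, at 2.24 and Nfkbia, the main NF-kappaB inhibitor, at 0.05. Among 28 cytokines and chemokines 13 were higher and 5 lower (median 0.29). Ccl5, a chemoattractant of T cells, stood at 488.7 and 2270 CPM (2.22), and Ccl17 at 1.43 and 10.9 (2.87). Ccl2, which recruits monocytes, was lower at 2664 and 1673 (-0.67), and Cxcl2, which recruits neutrophils, at 162.5 and 110.7 (-0.55). Of 40 interferon-stimulated genes 9 were higher and 2 lower (median 0.15), with Cxcl9, a chemokine for activated T cells, at 1.49 and the ubiquitin-like Isg15 at -0.84. Checkpoint and VISTA-related genes had 9 of 15 members higher and 0 lower (median 0.42), among them Pdcd1lg2, the PD-1 ligand PD-L2, at 4.55 and 27.4 CPM (2.57). MHC class I genes had 8 of 18 higher and 1 lower (median 0.23), with H2-Q7, which shares reads with H2-Q6, at 2.26. Cluster 6, held mostly by VISTA KO cells, has Cxcl9 and Ccl5 among its leading genes. Without it Ccl5 was at 1.53, Cxcl9 at 0.76, Pdcd1lg2 at 1.20, Bcl2a1d at 1.395 and Ccl2 at -0.31, and the NF-kappaB and interferon medians were 0.35 and 0.32. With each library clustered alone these values were 1.38, 0.50, 0.12, 0.77 and -0.84, and 0.05 and 0.31.

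Genes of MDSC function and myeloid identity went in both directions in monocyte-like cells. Of 28 immunosuppressive mediators 12 were higher and 3 lower (median 0.16). S100a8 and S100a9, alarmins of neutrophils and monocytes, had log2 ratios of -1.32 and -0.69, while Nos2, the inducible nitric oxide synthase, had 0.77 and Vegfa, an angiogenic factor, 0.78. The list median, Nos2 and Vegfa turned negative when each library was clustered alone, at -0.15, -1.15 and -0.29. Granule genes of early neutrophils had 8 of 11 members lower and 0 higher (median -0.88, but between -0.68 and -0.16 within single clusters), with Lcn2, a siderophore-binding granule protein, at 24.7 and 5.68 CPM (-2.11) and Serpinb1a, a protease inhibitor, at -1.10. Neutrophil RNA was also lower in VISTA KO in NK cell-like cells, where S100a8 stood at 93.1 and 10.1 CPM (-3.09, and -0.51 when each library was clustered alone). Of 19 late neutrophil genes 9 were higher and 3 lower (median 0.14), with Cxcr4, a bone marrow retention receptor, at 1.18 and G0s2, a lipase inhibitor, at -1.07. Of 23 myeloid transcription factors 8 were higher and 2 lower (median 0.25), with Nfe2l2, the oxidative stress regulator, at 0.76, Cebpa at 0.73 and Cebpe, a factor of granulocyte maturation, at -0.99. M2-associated genes had 7 of 18 higher and 2 lower (median 0.41, and -0.12 when each library was clustered alone), with Chil3, a chitinase-like protein, at -0.54 and Maf at -0.42.

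Metabolic genes were compared because the title names MDSC metabolism. Nuclear genes of oxidative phosphorylation had a median log2 ratio of -0.21 in monocyte-like cells, with 11 of 78 lower and 1 higher. Ndufa4, a subunit of respiratory complex IV, stood at 593.2 and 379.2 CPM (-0.65, -0.69 to -0.60) and Ndufb11, of complex I, at 294.3 and 208.3 (-0.50). Of the 13 mitochondrially encoded genes 4 were higher and 0 lower (median 0.17), with mt-Nd4l, of complex I, at 0.47. The nuclear list was also lower in cDC2-like (-0.16) and NK cell-like cells (-0.07), and the mitochondrially encoded list higher (0.32 and 0.23). Malat1, a nuclear RNA read as a sign of RNA quality, stood at 10148 and 13408 CPM over all kept cells. A difference in RNA quality was thus not told apart from one in metabolism. Glycolysis genes had 5 of 24 higher and 1 lower (median 0.04, and -0.28 when each library was clustered alone), with Gapdh at -0.31 and Eno1, which shares reads with a near-identical copy, at 0.59. Genes of pyruvate dehydrogenase and the TCA cycle had 0 of 24 higher and 3 lower (median -0.01), with Idh3a at -0.48 and Mdh2 at -0.43. Lipid uptake and fatty acid oxidation had 3 of 27 higher and 5 lower (median 0.01), with lipoprotein lipase, Lpl, at -0.77. The hypoxia list had 4 of 23 higher and 3 lower (median -0.07, and -0.22 without cluster 6), ATF4 and unfolded protein response genes 3 of 22 higher and 4 lower (median -0.02), and MYC targets and ribosome biogenesis genes 1 of 30 higher and 3 lower (median -0.13, and -0.24 without cluster 6), with the nucleotide kinase Nme1 at -0.63. S phase genes had 4 of 32 higher and 0 lower (median 0.14, and -0.01 with clusters weighted equally). G2 and M phase genes had 5 of 38 higher and 8 lower (median -0.09, and 0.13 when each library was clustered alone), with the mitotic cyclin Ccnb2 at -2.51. Dissociation and heat shock genes, read as a technical list, had 3 of 20 higher and 1 lower (median 0.07).

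**Figure D2:**
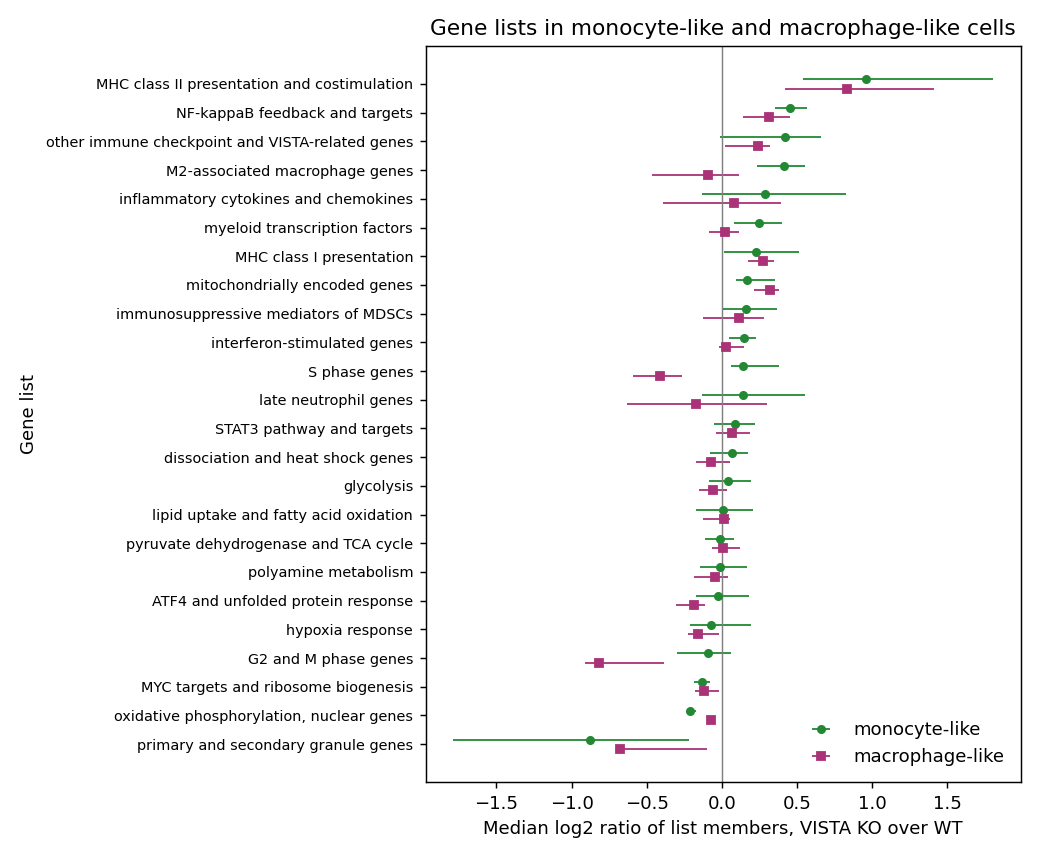
Median log2 ratio of list members (x axis, VISTA KO over WT, dimensionless) for 24 fixed lists in monocyte-like and macrophage-like cells, with lines for bootstrap 95% intervals over members. MHC class II stands highest in both classes, at 0.96 and 0.83, and the granule list stands at -0.88 and -0.68.

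Among all 8747 genes with at least 100 UMIs in monocyte-like cells, 659 were at least 1.5-fold higher and 144 at least 1.5-fold lower in VISTA KO with intervals that left out 1, a rule of size and not a test. Scaling by the median gene ratio, which shifted all ratios by 0.09 in log2, gave 470 and 213, counting genes from 20 UMIs gave 1012 and 226, and leaving out cluster 6 gave 395 and 132. Against random lists matched on expression, the MHC class II, NF-kappaB, M2-associated and interferon lists each ranked at the 100th percentile and the oxidative phosphorylation and granule lists at 0, a description of these libraries alone. Malat1, a nuclear RNA read as a sign of RNA quality, stood at 7631 CPM in WT and 11734 in VISTA KO monocyte-like cells.

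Polyamine and STAT3 genes were compared because the series title names both mechanisms. In monocyte-like cells most polyamine genes were close between the libraries: of 24 measured members 4 were higher, 2 were lower and the list median was -0.01. Slc7a2, which imports arginine and ornithine, stood at 11.7 CPM in WT and 38.5 in VISTA KO (log2 ratio 1.72, 1.49 to 1.97). Arg1 and Arg2, the arginases that make ornithine, had log2 ratios of 0.36 (0.32 to 0.39) and 0.69 (0.45 to 0.93), and Atp13a2, a lysosomal polyamine exporter, 0.59 (0.44 to 0.74). Odc1, the first enzyme of polyamine synthesis, was at 0.05 (-0.14 to 0.23). Of the later enzymes Amd1 and Srm were lower, at -0.48 (-0.91 to -0.06) and -0.41 (-0.76 to -0.06), while Sms, at -0.25 (-0.47 to -0.02), did not pass the size rule. Eif5a, the translation factor that carries hypusine made from spermidine, was at -0.26, and Oaz1, the antizyme that marks Odc1 for breakdown, at -0.24. Without cluster 6, Slc7a2 was at 0.44, Arg1 at -0.01 and Arg2 at 0.27, while Amd1 was at -0.64 and Srm at -0.50. With each library clustered alone, which left a VISTA KO cluster like cluster 6 unnamed, Slc7a2 was at -0.55 and Arg1 at -0.99.

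STAT3 and its targets were mostly close between the libraries in monocyte-like cells, with 6 of 30 measured members higher in VISTA KO, 1 lower and a median of 0.09. Within single monocyte clusters the list median lay between 0.09 and 0.24, and with the clusters weighted equally it was 0.16. Stat3 itself stood at 137.3 and 163.4 CPM (0.25, 0.17 to 0.33). Socs3, the feedback inhibitor that STAT3 induces, was at 251.5 and 359.4 (0.52, 0.46 to 0.57). Csf3r, the G-CSF receptor, was at 0.70 (0.56 to 0.84), Icam1, an adhesion molecule, at 0.52 (0.41 to 0.63), Bcl3 at 0.34 and Hif1a at 0.20. Birc5, the apoptosis inhibitor survivin, was at -1.09 (-1.76 to -0.49), from 67 and 33 UMIs, and at 0.24 when each library was clustered alone. Osm was at -0.29 and Cebpb, a factor of emergency granulopoiesis, at -0.17. Without cluster 6, Stat3 was at 0.35, Socs3 at 0.53, Vegfa at 0.45, Icam1 at 0.25 and Osm at 0.03.

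**Figure D3:**
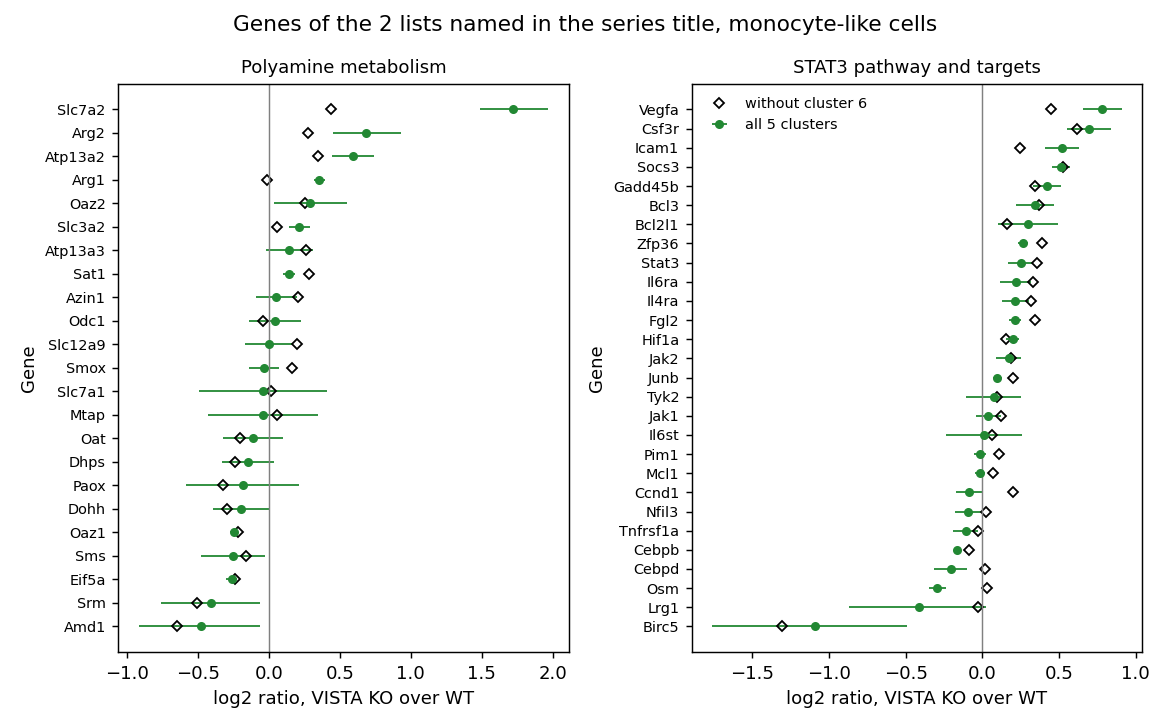
Log2 ratio (x axis, VISTA KO over WT) of polyamine genes (left) and STAT3 genes (right) in monocyte-like cells, with 95% counting intervals as lines and open diamonds for the value without cluster 6. Slc7a2 stands at 1.72 with all 5 clusters and at 0.44 without cluster 6.

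In macrophage-like cells, 1292 WT and 3587 VISTA KO, MHC class II genes were again higher in VISTA KO and cell cycle genes were lower over the class as a whole. Of 13 class II members 11 were higher and 0 lower (median 0.83, and 0.46 when each library was clustered alone), with H2-Eb1 at 1197 and 3542 CPM (1.56, 1.53 to 1.60) and H2-Aa at 1.54. MHC class I genes had 6 of 18 higher and 0 lower (median 0.27), with H2-T23, a nonclassical class I gene, at 0.81. NF-kappaB genes had 9 of 20 higher and 0 lower (median 0.32), with Tnfaip2 at 0.64. Of 51 measured G2 and M phase genes 29 were lower and 0 higher (median -0.82), and of 38 S phase genes 14 were lower and 0 higher (median -0.41). The G2 and M phase list took 0.129% of WT and 0.0970% of VISTA KO macrophage-like UMIs. With cells thinned to 1000 UMIs the shares of macrophage-like cells with a UMI of the list were close, at 54.9% in WT (30 left out, 94.1% unthinned) and 54.5% in VISTA KO (103 left out, 91.6% unthinned), and for S phase genes at 36.3% and 36.3%. Cdca3, a mitotic regulator, was at -1.80, Kif11, a spindle motor, at -1.40 and Uhrf1, which helps maintain DNA methylation, at -1.02. Within single macrophage clusters the G2 and M phase median was 0.05 in cluster 0, -0.06 in cluster 11 and -0.18 in cluster 12, and with the clusters weighted equally it was -0.06. The S phase median was -0.10, 0.02 and -0.09 in the same clusters, and -0.09 with the clusters weighted equally.

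Cytokines and chemokines in macrophage-like cells went both ways, with 8 of 25 higher and 8 lower (median 0.08). Ccl5 stood at 529.7 and 1602 CPM (1.60, 1.55 to 1.64), while Cxcl2 was at 516 and 219.7 (-1.23) and Ccl7, a monocyte attractant, at -0.73. Interferon-stimulated genes had 8 of 40 higher and 3 lower (median 0.03), with Cxcl9 at 1.22 and Isg15 at -0.95. Immunosuppressive mediators had 5 of 29 higher and 4 lower (median 0.11), with S100a9 at -1.93. M2-associated genes had 3 of 18 higher and 6 lower (median -0.09), with Retnla, a secreted product of IL-4 activated macrophages, at 22.4 and 3.66 CPM (-2.60), Folr2 at -0.86 and Mgl2 at 1.02. Checkpoint genes had 4 of 16 higher and 0 lower (median 0.24, and -0.04 in thinned cells), with Pdcd1lg2 at 1.93. Granule genes had 0 of 9 higher and 4 lower (median -0.68), late neutrophil genes 5 of 20 higher and 8 lower (median -0.17) and myeloid transcription factors 3 of 24 higher and 2 lower (median 0.02), with G0s2 at -2.06 and Cebpe at -0.81. Neutrophil RNA was lower in VISTA KO beyond these cells too, with S100a9 at -1.84 in NK cell-like cells, though at 0.12 there when each library was clustered alone, and over all classes 35.2% of WT and 8.44% of VISTA KO droplets with at least 10 C1q UMIs held at least 10 UMIs of S100a8 and S100a9.

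Polyamine genes in macrophage-like cells had 3 of 24 members higher and 2 lower (median -0.05). Slc7a2 was at 18.2 and 46.7 CPM (1.35, 1.11 to 1.62), Srm at -0.43 (-0.70 to -0.16), Sms at -0.42 (-0.59 to -0.25) and Odc1 at 0.00 (-0.15 to 0.15). STAT3 and its targets had 6 of 31 higher and 2 lower (median 0.06), with Socs3 at 0.79 (0.69 to 0.90), Hif1a, the hypoxia factor, at 0.65 (0.56 to 0.73), Stat3 at 0.14 (0.02 to 0.26) and Birc5 at -1.31. Nuclear oxidative phosphorylation genes had 1 of 78 higher and 2 lower (median -0.07), with Ndufa4 at -0.52 and Cycs, cytochrome c, at -0.36. Mitochondrially encoded genes had 6 of 13 higher and 0 lower (median 0.32), beside Malat1 at 9982 and 12841 CPM. Glycolysis had 5 of 24 higher and 2 lower (median -0.06), the TCA list 3 of 24 and 0 (median 0.01) and lipid genes 2 of 27 and 5 (median 0.02), with the fatty acid transporter Cd36 at -0.93. The hypoxia list had 2 of 24 higher and 6 lower (median -0.16), with Adm, a vasodilator peptide, at -1.01. ATF4 targets had 0 of 22 higher and 4 lower (median -0.18), MYC targets 0 of 30 and 2 (median -0.12) and heat shock genes 1 of 20 and 4 (median -0.07), with Hsp90aa1 at -0.51. Among 9110 genes with at least 100 UMIs, 312 were at least 1.5-fold higher and 227 at least 1.5-fold lower, while 384 were lower when genes were counted from 20 UMIs and 147 when genes that mark the library were kept out of the clustering.

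Most of the genes farthest apart between the libraries in all kept cells lie on chromosome 1, which also holds Ptprc, the CD45 gene by which the donors differ. The genes with the lowest ratios in monocyte-like cells (Chil1, Ifi213, Npl, Ctse and Ifi206) and the highest (Ppfia4, Ifi202b and Fcrla) lie there too. In NK cell-like cells most of the named genes lie elsewhere. In all kept cells Chil1, a chitinase-like lectin, stood at 118.6 CPM in WT and 1.33 in VISTA KO (log2 ratio -6.46). Npl, a sialic acid lyase, was at -4.36 and Ctse, the protease cathepsin E, at -4.12. On the higher side, Ppfia4 was at 0.616 and 38.5 CPM (5.93) and Fcrla, an Fc receptor-like protein, at 5.06. 3 prime tags of the Ifi200 family of interferon-inducible DNA sensors may share reads between near-identical copies and are uncertain gene by gene: Ifi202b was at 6.59, Ifi213 at -5.53 and Ifi206 at -3.14. Outside chromosome 1, Pianp on chromosome 6 was at 5.32 and Mid1 on chromosome X at 3.03. In monocyte-like cells Chil1 was at -10.46 (-16.77 to -8.98), from 2651 and 1 UMIs. Other leading genes there were Pltp, a phospholipid transfer protein, at 2.54 (1.97 without cluster 6), Zmynd15 at 2.54 (1.71), Anpep, the surface aminopeptidase CD13, at 2.40 (1.03), Stmn1, a microtubule regulator, at -1.88 and Pttg1, the mitotic securin, at -1.79. In macrophage-like cells they included Eno2, a neuronal-type enolase on chromosome 6, at 4.65, F11r, a junction protein, at -1.98 and Wdr89 at -1.79.

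The mixed neutrophil and macrophage droplets, the named class whose share differed most in percentage points, were compared next. MHC class II genes were higher in VISTA KO there too, with 10 of 13 higher and 0 lower (median 0.66), and 10 of 13 mitochondrially encoded genes were higher (median 0.41). Malat1, read as a sign of RNA quality, stood at 11155 and 13401 CPM in these droplets. Late neutrophil genes had 2 of 21 higher and 9 lower (median -0.13), granule genes 0 of 11 and 4 (median -0.33) and cytokines 7 of 27 and 10 (median -0.11). Polyamine genes had 2 of 24 higher and 2 lower (median 0.03), with Slc7a2 at 1.32 (1.14 to 1.49) and Smox, which oxidises spermine, at -0.38 (-0.48 to -0.28). STAT3 genes had 5 of 31 higher and 5 lower (median 0.02), with Vegfa at 0.62, Socs3 at 0.48 and Mmp9, a matrix protease, at -0.47. The genes farthest apart were Pianp (6.56), Ifi202b (6.43), Eno2 (5.77) and Ifi213 (-5.67). Since this class as a whole carried RNA of both cell types, these ratios cannot be assigned to either.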

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

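The alternatives with mixed and unnamed clusters left out, the highest doublet scores left out, genes that mark the library kept out of the clustering or of the counts, cluster 6 left out and clusters weighted equally were chosen after the data were seen, and the others were planned. All 45 alternative values of the 5 share differences kept their sign, 24 of them within the counting interval. Of 330 alternative list medians 281 stayed within their interval, 45 moved and 4 reversed. Of 2361 single gene values 1662 stayed, 648 moved and 51 reversed. A list median or gene value counted as reversed only where its reported interval left out 0. Other changes of sign are among the values that stayed or moved. The neutrophil share difference lay between -17.4 and -15.8 points except with mixed and unnamed clusters left out. Polyamine medians lay between -0.13 and 0.08 in monocyte-like cells. The cause was not tested except where a setting's own construction gives it. Depth limited genes near 100 UMIs and classes near 100 cells.

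Share differences below are VISTA KO minus WT in percentage points. With mixed and unnamed clusters left out, which shrinks the denominator and takes mixed droplets out of the neutrophil class, the neutrophil difference was -5.25, monocyte-like -8.00, macrophage-like 18.0, NK cell-like -3.63 and T cell-like -2.07. The monocyte-like and macrophage-like differences were -9.52 and 7.47 with the stricter cell filter, -7.27 and 8.39 with doublets kept, -7.10 and 14.8 at Leiden resolution 0.5, and -11.2 and 7.31 at resolution 2. They were -12.9 and 13.6 with the highest doublet scores left out, and -9.68 and 4.40 with genes that mark the library kept out of the clustering. With no lower limit on genes and UMIs the monocyte-like difference was -10.5. With each library clustered alone the differences were -13.6 for monocyte-like, 3.07 for macrophage-like and -0.977 for NK cell-like cells. Doublets kept differs from the main setting by 1 droplet only. With no lower limit at most 6 WT and 2 VISTA KO barcodes are added. These 2 settings thus show how far clustering and naming alone move these shares, for monocyte-like cells from -5.56 to -10.5.

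For the MHC class II, oxidative phosphorylation and cell cycle lists, and for the counts and tags, the values that moved are given here, while the moved medians of other lists are counted above only. With each library clustered alone, MHC class II in monocyte-like cells was 0.27, G2 and M phase in monocyte-like 0.13, oxidative phosphorylation in macrophage-like -0.12 and S phase in macrophage-like -0.19. With genes that mark the library kept out, oxidative phosphorylation in macrophage-like was -0.11 and 147 genes were at least 1.5-fold lower there. Median-ratio scaling gave -0.30 for oxidative phosphorylation and 0.054 for S phase in monocyte-like, and -1.64 for Vsir over all kept cells. Equal weight per cell gave -0.25 for oxidative phosphorylation in monocyte-like and -0.26 for S phase in macrophage-like. Thinned cells gave -0.23 for oxidative phosphorylation and 0.066 for G2 and M phase in monocyte-like, and -0.047 for oxidative phosphorylation and -0.23 for S phase in macrophage-like. Leaving out cluster 6 gave -0.24 for oxidative phosphorylation and 395 genes at least 1.5-fold higher in monocyte-like. Equal weight per cluster gave -0.0097 for S phase (reversed) and 0.093 for G2 and M phase in monocyte-like. In macrophage-like it gave -0.10 for oxidative phosphorylation, -0.087 for S phase and -0.060 for G2 and M phase. The G2 and M phase medians given here for monocyte-like cells also changed sign. They count as moved because the reported interval held 0. From 20 UMIs, which admits more genes, 1012 were higher and 226 lower in monocyte-like and 384 lower in macrophage-like. As shares of all tag UMIs, the log2 ratio was -0.18 for Ly6G in neutrophil-like cells, -0.62 for Ly6G in mixed neutrophil and macrophage droplets, -0.0047 for Ly6C in monocyte-like and 0.36 for CD11c in macrophage-like cells.

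Log2 ratios that reversed when each library was clustered alone were, in monocyte-like cells, Aldoc -0.31, Arg1 -0.99, Bcl2a1b -0.42, Bcl2l1 -0.10, Birc5 0.24, Cebpd 0.46, Clec4n -0.35, Gadd45b -0.096, Gas2l3 -0.14, Junb -0.0058, Lyz2 0.26, Mgl2 -0.59, Nfkbia -0.20, Nos2 -1.15, Olr1 -0.056, Slc3a2 -0.078, Slc7a2 -0.55, Tnfrsf1a 0.087, Tnfrsf9 -0.94, Vegfa -0.29 and mt-Nd4 0.14. The medians of MDSC mediators and M2-associated genes there were -0.15 and -0.12. Since this setting left a VISTA KO cluster like cluster 6 unnamed, the monocyte-like classes it compares are not like for like. In macrophage-like cells Bhlhe41 was 0.15, Lyz2 -0.020 and mt-Nd4 -0.048, and in NK cell-like cells S100a9 was 0.12. Under the stricter filter S100a9 was 0.61 in cDC2-like, Arg2 -0.038 in macrophage-like, and Lgals9 0.068, Lyz2 0.033, Nfkbia -0.055 and Olr1 -0.0061 in monocyte-like cells. With equal weight per cell Arg1 was -0.021 and Sat1 -0.013 in macrophage-like and mt-Nd4 0.042 in monocyte-like cells. In thinned cells Azin2 was -0.14, Eif5a 0.062, Il6ra -0.033, Nectin2 -0.31, Sat1 -0.013 and the checkpoint median -0.044 in macrophage-like, and Oaz2 -0.21 and Rfc2 0.069 in monocyte-like cells. Without cluster 6, monocyte-like Arg1 was -0.012, Atp5g2 -0.0013, Cebpd 0.018, Lgals9 0.067, Lyz2 0.051, Nfil3 0.026, Nos2 -0.34 and Osm 0.029. Median-ratio scaling gave Nfkbia -0.039 in monocyte-like cells.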

Other observations

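All tests of the 3 patterns weighed here were chosen after the result was seen, and the values given first belong to no test.

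Marker lists of other cell types also differed between the libraries. Erythroid genes, mainly hemoglobins, stood at 2.16 CPM in WT and 110 in VISTA KO, from 133 and 8808 UMIs. No cluster was named erythroid, and the source of this RNA was not tested. T cell markers stood at 86.6 and 26.6, NK cell markers at 843.3 and 513.2, and mature dendritic cell markers, which include Ccl5, at 1126 and 2154. Endothelial markers, some of which myeloid cells share, were at 80.9 and 121.1. Other lists were low or close: type 1 dendritic cell markers at 354.2 and 382.7, type 2 at 980.9 and 791.4, plasmacytoid dendritic cell at 78.2 and 99.03, B cell at 42.5 and 38.7, mast cell or basophil at 23.4 and 24.7, eosinophil at 4.12 and 2.26, early granulocyte at 27.0 and 15.04, tumor epithelial at 10.2 and 6.59, and fibroblast at 16.4 and 18.2.

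In cDC2-like cells, 459 WT and 715 VISTA KO, 14 of 22 myeloid transcription factors were higher and 0 lower in VISTA KO (median 0.36), as were 17 of 40 interferon-stimulated genes with 2 lower (median 0.29) and 13 of 28 STAT3 genes with 1 lower (median 0.31). The technical list of dissociation and heat shock genes was also higher there, with 6 of 20 higher and 0 lower (median 0.22), and Malat1 stood at 7245 and 9523 CPM. MHC class II differed little in these cells, with 2 of 13 higher (median 0.12), and hypoxia genes were lower in 8 of 22 with 3 higher (median -0.38). Ccl12, a monocyte chemokine, had a log2 ratio of 1.86 and Timd4, a receptor for dying cells, 2.80. In mature DC-like cells 8 of 12 mitochondrially encoded genes were higher and 0 lower (median 0.49), with Cxcl2 at -1.91 and Fabp4, a fatty acid carrier, at 3.08. Malat1 stood at 12959 and 17740 CPM in mature DC-like cells, and the median mitochondrial share of UMIs at 0.53% and 0.74%. In NK cell-like cells Ifi202b (6.73) and Ifi213 (-4.87) stood farthest apart, and RNA of other cell types also differed, with Thbs1 at 3.05, C1qb at 2.54 and S100a8 at -3.09. Mixed NK cell and macrophage droplets took 1.22% of WT and 1.29% of VISTA KO cells, and mixed cDC2 and macrophage droplets 1.70% and 1.57%. Y-linked genes had 0 UMIs in both libraries, with Xist at 290.9 and 357.1 CPM.

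Of neutrophil-like and mixed neutrophil and macrophage droplets together, 82.8% in WT and 91.0% in VISTA KO were mixed by the name of their cluster. That name was not set droplet by droplet. Over all classes 1141 WT and 507 VISTA KO droplets held at least 10 C1q UMIs and at least 10 UMIs of S100a8 and S100a9. Free neutrophil RNA is argued against, since a WT monocyte-like cell held 0.836% of the S100a8 UMIs of a WT mixed droplet. So is random loading, by droplets with at least 10 UMIs of S100a8 and S100a9 in the WT library. They made up 1.92% (1.03 to 3.26) of NK cell marker droplets with few or no C1q UMIs, against 35.2% of droplets with at least 10 C1q UMIs. Neutrophils engulfed whole before staining are argued against by the Ly6G tag, with a median of 83 per WT mixed droplet, 63 per neutrophil-like and 8 per macrophage-like cell. What stays open, as an untested hypothesis, is that neutrophils and macrophages may have been attached to each other in the tissue or the suspension, and the lower number of such droplets in VISTA KO has no replicate behind it. Mixed droplets held a median of 122% of the neutrophil marker UMIs of a neutrophil-like droplet in WT and 112% in VISTA KO over 12 markers, but in VISTA KO only 64.4% for S100a8, 61.1% for S100a9, 63.0% for Mmp9, 33.6% for Ly6g and 33.1% for Retnlg.

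Genes far apart between the libraries were more frequent on chromosome 1 around Ptprc, and also in some regions elsewhere. Of genes within 10 Mb of Ptprc, 9.33% (7 of 75) were at least 2-fold apart in all kept cells, against 2.86% (313 of 10964) outside the regions of Ptprc and Vsir and 2.78% (2 of 72) near Vsir, so a donor segment around Ptprc carried along with the CD45 allele is a candidate explanation, though the sources used here do not say which donor carried which allele. Reads shared within the Ifi200 family have no route to the 9 genes outside the family that were at least 4-fold apart within 40 Mb of Ptprc, 1 short of the 10 set as the bound, and for the 3 family members sharing and a true difference cannot be told apart. A response to VISTA loss cannot be told apart either: the median absolute log2 ratio was 3.27 over 6 of these genes in NK cell-like cells, but WT NK cell-like cells held 30.1% of the monocyte-like Vsir level, too much for this test to decide. In windows of 5 Mb the share at least 2-fold apart was 25.8% (17 of 66) at 170 to 175 Mb of chromosome 1. It was also 19.6% (10 of 51) at 120 to 125 Mb of chromosome 6, where Pianp and Eno2 lie. At 35 to 40 Mb of chromosome 16 it was 18.4% (7 of 38) and at 5 to 10 Mb of chromosome 17 20.8% (5 of 24). A segment around Ptprc does not account for the regions off chromosome 1. The windows pool all kept cells, so a different cell mix can enter them. Cstdc4, in the chromosome 16 window, is a leading gene of clusters 2 and 15, the mixed and neutrophil-like clusters, whose joint share was lower in VISTA KO. Of the 12 genes 11 went the same way in every class with at least 20 UMIs. They were chosen as at least 4-fold apart in all kept cells, which pool these classes, so this agreement is partly built in.

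MHC class II genes were higher in monocyte-like cells of the VISTA KO library. Free RNA is argued against as the whole cause, since the gain in NK cell-like cells was 18.6% of the gain in monocyte-like cells, and a different mix of clusters as the whole cause by a median of 0.64 within single clusters, between 0.44 and 1.33, against 0.96 for the class. A strain variant of the H2 region raising class II genes in every cell type is argued against by the cDC2-like list median of 0.12 (-0.06 to 0.18). A variant acting in some cell types only is not addressed, as the macrophage-like median was 0.83. H2-Q6, of the same region, was among the named highest genes in monocyte-like (2.75), macrophage-like (1.82) and mature DC-like cells (1.57). It was also among them in mixed NK cell and macrophage (1.89) and mixed cDC2 and macrophage droplets (2.35). In cDC2-like, NK cell-like and mixed neutrophil and macrophage droplets it was not. All genes named as highest in those classes lay above 1.57, so the ranking cannot show that H2-Q6 differed little there. A part of the difference may still come from cell mix, as the list median was 0.56 without cluster 6. The value with each library clustered alone, 0.27, cannot decide this, since a VISTA KO cluster with leading genes of cluster 6 was left unnamed there. Loss of VISTA in these cells stays open and untested with 1 library per group.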
